A study of Mus musculus with 27 samples.

How the data were processed

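Total RNA from 3T3-L1 cells carrying an empty vector or Flag-ISL1 was measured on 27 Affymetrix mouse gene arrays, 1 array per sample, in 9 groups of 3. The labels state that RNA was extracted with a column kit, labelled with biotin and fragmented. The series design text calls the arrays of a group biological triplicates. The authors named RMA (background correction, quantile normalization and probe summary) as the processing, and its software and version are not given in the sources used here. The deposited values are on the log2 scale: the labels do not state the base, and it was settled from the values, which run from 3.35 to 14.85 as RMA output does. The arrays have close but not identical quantiles. The table holds 28853 probe sets with 0 missing values, and values were used as deposited.

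Probe sets were joined to genes by the platform's gene table. Of the probe sets 21789 had 1 gene symbol, 1621 had several and 5443 had none, and only the first kind was used. For 21698 of them the Entrez ID was also found in the RefSeq gene table of the GRCm38.p6 assembly, which served for symbols and gene order only, since the labels name no genome build. For the 999 genes with more than 1 probe set the one with the highest mean was kept, which left 19938 genes. Intensity over background was not tested with detection calls, which were not used here, and the number of arrays per group limits the precision of each value.

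Groups were taken from the sample labels (construct and hours in medium). A linear model with 1 mean per group was fitted to all 27 arrays with limma 3.58.1 in R 4.3.3, with variances moderated by empirical Bayes (prior degrees of freedom 6.56). There were 15 comparisons: vector cells at each time against 0 h, each time against the one before, ISL1 against vector at 0 h and at 48 h, ISL1 at 48 h against 0 h, and the difference of the ISL1 effect between the times. P-values were adjusted by Benjamini and Hochberg over the 19938 genes within each comparison, and genes with an adjusted p under 0.05 were counted, with those of at least a 2-fold change beside them. An F test over the 7 vector groups asked for any change over time. The tests of genes and of lists were two-sided.

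Fixed before the data were examined were the groups, the comparisons, the tests, the gene lists, the alternatives not marked as later additions and the rule for naming genes. The 32 lists, written from general knowledge of the pathways, held 835 entries for 764 distinct genes, and 786 entries were measured. They covered immediate early genes, early adipogenic transcription factors, adipocyte markers, adipogenesis repressors and preadipocyte genes, BMP ligands with receptors and antagonists, BMP targets, Wnt and Notch signalling, TGF-beta targets, matrix and cytoskeleton, DNA replication, mitosis, glucocorticoid targets, cAMP targets, the circadian clock, cholesterol synthesis, fatty acid and triglyceride synthesis, inflammatory and NF-kB targets, interferon response, lineage genes linked to ISL1 and Hox genes. The rest were osteoblast and chondrocyte, muscle, macrophage and other blood cell, endothelial and epithelial markers, brown and beige fat genes, unfolded protein and amino acid responses, ribosome biogenesis, oxidative phosphorylation, p53 targets, and heat shock and oxidative stress genes. The lists share genes, so their results are not independent. The names of members without a probe set of 1 gene symbol are not reported here.

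Each list was tested against the other genes with camera at a preset correlation of 0.01, with Benjamini and Hochberg adjustment over the 480 tests of 32 lists in 15 comparisons, and again with the correlation estimated from the residuals. The counts of members past the test were taken from the adjustment over all genes, and again after adjustment over the list alone.

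Genes are named by this rule. Always named were Isl1, Bmp4, Pparg, Cebpa, Cebpb and Cebpd. Added for each comparison were the 10 largest rises and 10 largest falls past the test in which all 3 arrays of one group lie beyond the 3 of the other, and, of each list, the 4 members past the test with the largest change and the 2 largest that moved against the list's majority. For the difference of effects only the adjusted p was required. Names outside the rule are marked as chosen after their values were seen.

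The fit was tested on simulated data with the same groups. At 0 h, 88.1% of 67 genes changed 1.5-fold were recovered, and 100% of the genes changed 2-fold and 4-fold. Of 198 calls 6 were false (3.03%). The unchanged comparisons gave 0 calls by limma. The noise was drawn independently for each gene and array, unlike the residuals of the data described below. These shares therefore do not measure error control on the data.

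Correlations between effects that share arrays were set beside 100 simulations without effects, also with independent noise. Replicate numbers were checked for pairing: of 36 pairs of groups 4 had all 3 same-number residual correlations above 0.1, and 9 of 27 arrays correlated best with an array of their own number. The 4 were the 2 groups at 48 h (0.314, 0.547 and 0.217) and the pairs among vector 0.5, 1 and 4 h. Arrays were not treated as paired, so that any pairing at 48 h is left out of the standard errors there. The replicate number as a block assumes 1 effect shared by all groups. The first component of the within-group residuals held 41.5% of their variance and followed the spread of the array values (interquartile range 3.1 to 3.47) at r = 0.99. Arrays of a group correlated at 0.9931 to 0.9986, and the median SD of a gene within groups was 0.114. The sample records fall into 3 blocks by their order in the database, with the 0 h, the 0.5 to 8 h and the 48 h arrays apart, and whether these were also processing batches is not given in the sources used here. If they were, time and batch cannot be told apart in comparisons of times from different blocks, while ISL1 and vector at one time lie within a block. The 0 h and 0.5 h arrays come from different blocks and differed in 255 genes.

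Alternatives were quantile normalization again, median centring, leaving out the 40% dimmest genes, the mean of a gene's probe sets, a trend and robust variance prior, array weights, fits of only the arrays compared, the replicate number as a block, an estimated list correlation and leaving out each array in turn. Chosen after seeing the data were the 48 h labels exchanged, the array spread as a covariate, the F test without the 48 h arrays, and the replicate number as a block within the 48 h arrays and within the vector 0.5, 1 and 4 h arrays. With the labels exchanged, list tests were adjusted only over the comparisons that hold 48 h arrays. With an estimated correlation, the DNA replication list at 48 h thus had camera adjusted p = 0.0461 as labelled and 0.0395 exchanged. List calls near 0.05 under the 2 labellings are therefore not strictly comparable. A change of pseudocount was not run because the values are already logarithms. Microarray signals of probe sets without a single gene symbol, isoforms and DNA copy number were not analysed here. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.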

Results

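The series holds 27 arrays of total RNA from 3T3-L1 cells, a mouse fibroblast line that turns into fat cells when given a hormone mixture. The cells carried either an empty retroviral vector or the same vector with Flag-tagged ISL1, a LIM homeodomain transcription factor. They were grown to confluence and, 2 days later, were given medium with 10% serum, 350 nM insulin, 0.5 mM IBMX (which raises cAMP), 250 nM dexamethasone (a glucocorticoid) and 400 nM biotin. Vector cells were sampled at 0, 0.5, 1, 2, 4, 8 and 48 h and ISL1 cells at 0 and 48 h, which makes 9 groups of 3 arrays. The 0 h cells were taken just before the mixture was added. Each array gave log2 intensities between 3.35 and 14.85, and 19938 genes were tested. The number of arrays per group limits the precision of every value. Changes are given as log2 differences ± the standard error of the limma fit, with n = 3 arrays in each group. For each of the largest rises and falls named, all 3 arrays of one group lay beyond all 3 of the other.

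The construct could be followed only through the Isl1 probe set. Whether that probe set measures the Flag-ISL1 transcript, and from which species the construct's sequence comes, is not given in the sources used here. At 0 h the Isl1 level was 7.34 ± 0.157 (mean ± SD, n = 3) in vector cells and 12.62 ± 0.018 in ISL1 cells. At 48 h it went against the labels: it was 7.65 ± 0.306 in the arrays labelled ISL1 and 12.76 ± 0.036 in those labelled vector. The 3 arrays labelled ISL1 48 h read 7.48, 8.01 and 7.47, and the 3 labelled vector 48 h read 12.79, 12.76 and 12.72. No array was reassigned, so every direction at 48 h is given as labelled, and the numbers of genes past the test with the labels exchanged, an alternative chosen after seeing the data, stand beside it. In vector cells before 48 h, Isl1 was 7.36 ± 0.078 at 0.5 h, 8.59 ± 0.09 at 2 h and 8.02 ± 0.064 at 8 h. Bmp4, the ligand of the BMP pathway in the study's title, was 11.77 ± 0.05 in vector cells and 8.22 ± 0.065 in ISL1 cells at 0 h. Its level was 7.71 ± 0.152 and 7.48 ± 0.238 in the arrays labelled ISL1 and vector at 48 h.

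**Figure D1:**
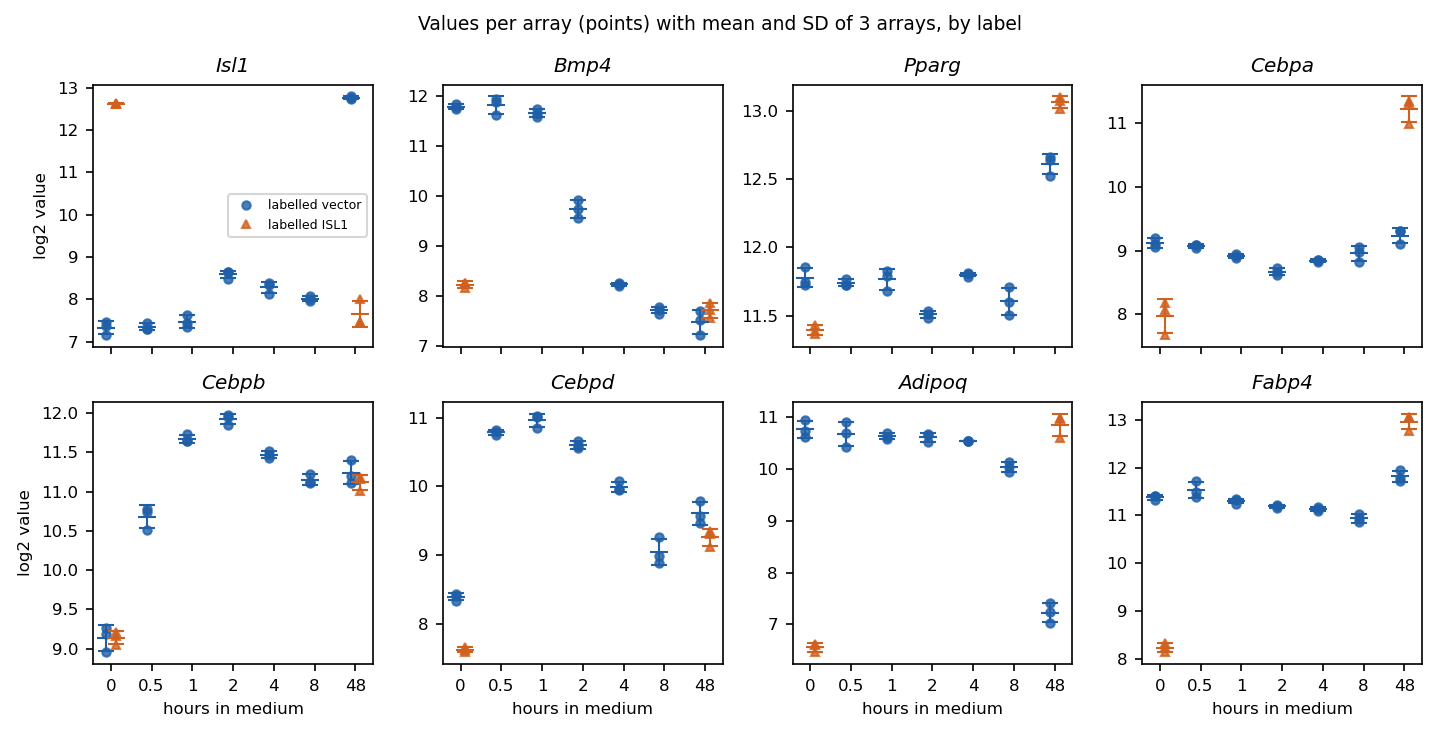
Log2 value of 8 genes on each array (points) with the mean and SD of 3 arrays, against hours in the differentiation medium, coloured by the construct on the label. Isl1 is high in the ISL1 group at 0 h (mean 12.62) and in the group labelled vector at 48 h (mean 12.76).

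The number of genes that differed from 0 h in vector cells grew up to 8 h. Against 0 h, 255 genes passed the test at 0.5 h (155 higher, 100 lower), 1410 at 1 h (554 higher, 856 lower). There were 5649 at 2 h (2167 higher, 3482 lower), 7990 at 4 h (3459 higher, 4531 lower) and 9187 at 8 h (4822 higher, 4365 lower). With at least a 2-fold change, the numbers higher and lower were 61 and 10, 143 and 27, 377 and 238, 626 and 613, and 607 and 770. Any change over the 7 times of the vector arrays was found for 11256 genes, 56.5% of those tested. Without the 48 h arrays this number was 10440, and with the 48 h labels exchanged it was 11205, both alternatives chosen after seeing the data. Median centring of the arrays moved the share of higher genes among the calls from 39.3% to 51.8% at 1 h and from 38.4% to 48.6% at 2 h.

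**Figure D2:**
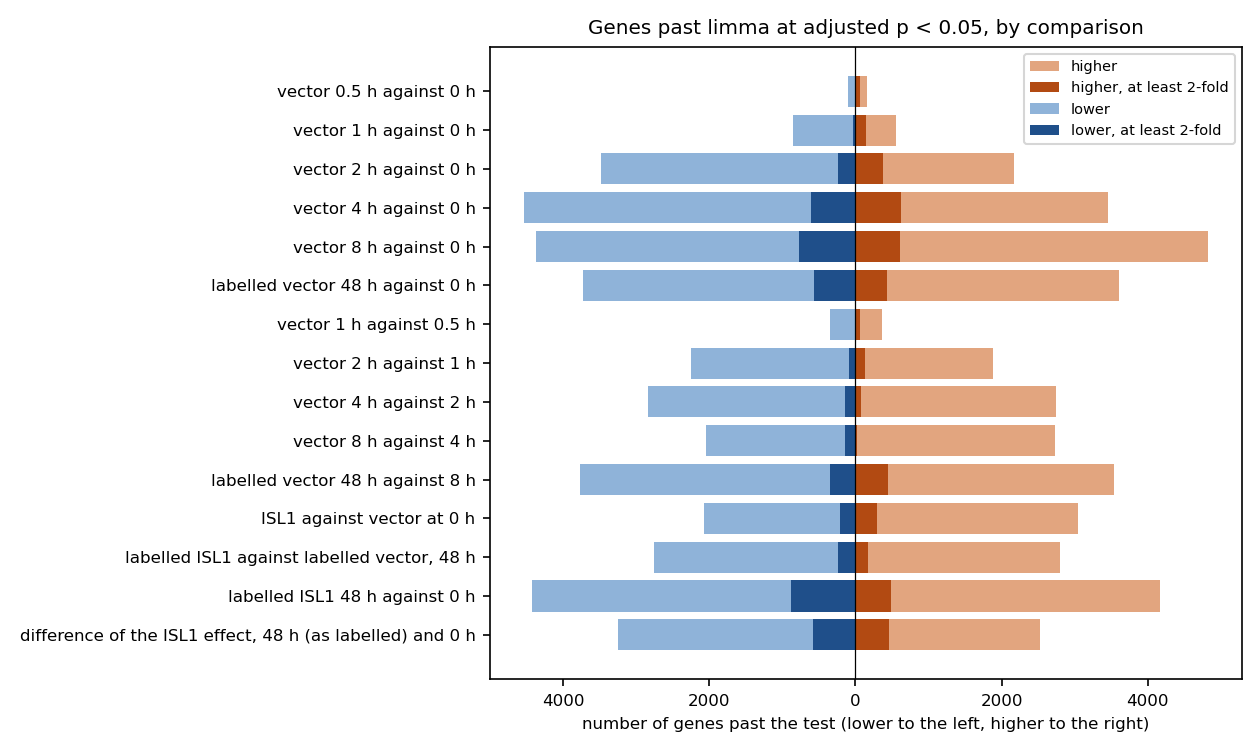
Number of genes past limma's test at adjusted p < 0.05 in each of the 15 comparisons, with lower genes to the left and higher genes to the right, and the part with at least a 2-fold change in the darker colour. Among the comparisons of vector cells with 0 h, the number grew from 255 at 0.5 h to 9187 at 8 h.

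At 0.5 h the immediate early genes, which are switched on without new protein synthesis, led the response in vector cells. Fos rose by 4.39 ± 0.103, Nr4a1 by 4.14 ± 0.064, Btg2 by 3.99 ± 0.096, Egr1 by 3.16 ± 0.081 and Fosb by 3.03 ± 0.096. The phosphatase gene Dusp1 rose by 3.22 ± 0.074, the RNA decay factor gene Zfp36 by 3.45 ± 0.082 and Ptgs2, which encodes the inducible cyclooxygenase, by 4.34 ± 0.104. Of the 29 measured immediate early genes 26 rose and the other 3 did not pass, or 28 rose and 1 fell when adjusted over the list alone (median 1.54, camera adjusted p = 2.82e-190, and adjusted p = 7.64e-08 with an estimated correlation). Of the cAMP targets 16 of 29 rose (also 16 adjusted over the list alone, median 0.62, camera adjusted p = 4.64e-76, and adjusted p = 1.32e-06 with an estimated correlation). So did 13 of 28 glucocorticoid targets (14 adjusted over the list alone, median 0.27, camera adjusted p = 1.54e-43, and adjusted p = 3.77e-06 with an estimated correlation). Among the latter, Per1 rose by 1.15 ± 0.065 and the metallothionein genes Mt1 and Mt2 by 1.32 ± 0.061 and 1.47 ± 0.086.

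The regulators Cebpb and Cebpd, which act early in fat cell formation, already rose by 1.54 ± 0.086 and 2.39 ± 0.086 at 0.5 h, while Cebpa (-0.05 ± 0.101), Pparg (-0.04 ± 0.06), Bmp4 (0.04 ± 0.104) and Isl1 (0.02 ± 0.107) did not pass the test. BMP target genes rose, with 5 of 19 past the test (8 adjusted over the list alone, camera adjusted p = 3.81e-12, and adjusted p = 0.000295 with an estimated correlation), among them Id1 (1.10 ± 0.085), Id2 (1.06 ± 0.071) and Id3 (1.84 ± 0.076). Of the inflammatory and NF-kB targets 6 of 28 rose (8 adjusted over the list alone, camera adjusted p = 2.72e-19, and adjusted p = 5.64e-06 with an estimated correlation). Il6 rose by 2.43 ± 0.176 and the chemokine gene Cxcl1 by 2.49 ± 0.126. Early adipogenic transcription factors also moved up (8 of 21 higher, camera adjusted p = 1.51e-17, and adjusted p = 0.0079 with an estimated correlation). Of the adipogenesis repressors 6 of 26 rose (camera adjusted p = 2.98e-09, and adjusted p = 0.0145 with an estimated correlation). The largest falls were in probe sets of microRNA genes, Mir199b (-2.19 ± 0.123) and Mir130a (-1.60 ± 0.104), and in the transcript C030016D13Rik (-1.78 ± 0.126). The largest adjusted p among the genes named as changed at 0.5 h was 5.79e-10.

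At 1 h immediate early genes, glucocorticoid targets and cAMP targets were again higher on the whole than at 0 h. Ptgs2 rose by 5.46 ± 0.104, Nr4a3 by 4.83 ± 0.116, Nr4a1 by 4.70 ± 0.064, Egr2 by 4.48 ± 0.113, Il6 by 4.12 ± 0.176 and Fos by 4.09 ± 0.103. Nfil3, a transcriptional repressor gene, rose by 3.36 ± 0.075, Csrnp1 by 3.57 ± 0.114, Tcim by 3.71 ± 0.108 and Gadd45g by 2.38 ± 0.094. Of the immediate early genes 28 of 29 rose and 1, Klf10 (-0.79 ± 0.074), fell (the same counts adjusted over the list alone, median 2.75, camera adjusted p = 2.86e-137, and adjusted p = 5.55e-07 with an estimated correlation). Glucocorticoid targets rose in 17 of 28 cases and fell in 2 (19 and 2 adjusted over the list alone, median 0.90, camera adjusted p = 2.05e-46, and adjusted p = 3.27e-06 with an estimated correlation). Per1 rose by 1.96 ± 0.065, Mt1 by 2.13 ± 0.061 and Mt2 by 2.27 ± 0.086. Of the cAMP targets 20 of 29 rose (21 higher and 1 lower adjusted over the list alone, median 1.01, camera adjusted p = 2.83e-63, and adjusted p = 3.27e-06 with an estimated correlation).

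Cebpb rose by 2.54 ± 0.086 and Cebpd by 2.57 ± 0.086 at 1 h. The BMP target list had 8 higher and 1 lower of 19 (camera adjusted p = 5.15e-10, and adjusted p = 0.000722 with an estimated correlation). Id1 rose by 1.75 ± 0.085, Id3 by 2.12 ± 0.076 and Smad7 by 1.01 ± 0.068. Heat shock and oxidative stress genes rose in 8 of 20 cases (10 adjusted over the list alone, camera adjusted p = 8.4e-17, and adjusted p = 0.0069 with an estimated correlation), with Gclc, which encodes the catalytic subunit for glutathione synthesis, at 1.49 ± 0.074 and the chaperone gene Dnajb1 at 1.46 ± 0.104. Of the inflammatory and NF-kB targets 12 of 28 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 1.18e-20, and adjusted p = 3.77e-06 with an estimated correlation), with Nfkbia up by 1.80 ± 0.081 and Irf1 down (it fell by 1.01 ± 0.106). Early adipogenic transcription factors rose in 9 of 21 cases and fell in 1 (camera adjusted p = 3.95e-16, and adjusted p = 0.0115 with an estimated correlation). Hox genes, which pattern the body axis, fell in 8 of 27 cases and the other 19 did not pass (1 higher and 10 lower adjusted over the list alone, median -0.18, camera adjusted p = 0.000269, and adjusted p = 0.0285 with an estimated correlation), among them Hoxa3 (-0.53 ± 0.09) and Hoxd4 (-0.52 ± 0.084). Zinc finger genes stood among the largest falls. Zfp418 fell by 1.48 ± 0.125 and Zfp157 by 1.30 ± 0.111, next to the glycogen-targeting gene Ppp1r3c (-1.38 ± 0.109). Isl1, Bmp4, Pparg and Cebpa did not pass at 1 h. The largest adjusted p among the genes named as changed was 0.000148.

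Many falls had joined the rises by 2 h. Bmp4 fell by 2.04 ± 0.104 (adjusted p = 1.74e-14), the insulin receptor substrate gene Irs1 by 2.45 ± 0.085, Cdc42ep3 by 2.72 ± 0.12, the clock repressor gene Nr1d1 by 2.23 ± 0.083 and Irf1 by 2.21 ± 0.106. Pparg fell by 0.27 ± 0.06 and Cebpa by 0.45 ± 0.101, whereas Cebpb stood 2.79 ± 0.086 and Cebpd 2.21 ± 0.086 above 0 h and Isl1 rose by 1.26 ± 0.107 (adjusted p = 5.42e-10). Among the largest rises were Nr4a3 (5.42 ± 0.116), Tcim (5.21 ± 0.108), Ptgs2 (4.64 ± 0.104), Nr4a1 (4.56 ± 0.064), Fgl2 (3.99 ± 0.125) and Fosl1 (3.78 ± 0.092). Glucocorticoid targets were higher in 19 of 28 cases and lower in 2 (20 and 2 adjusted over the list alone, median 1.40, camera adjusted p = 3.25e-21, and adjusted p = 0.000295 with an estimated correlation), led by the co-chaperone gene Fkbp5 at 3.53 ± 0.068. Immediate early genes still stood higher in 26 of 29 cases and lower in 2 (median 1.96, camera adjusted p = 2.19e-42, and adjusted p = 0.000379 with an estimated correlation). The cAMP targets stood higher in 21 of 29 with 6 lower (camera adjusted p = 6.98e-21, and adjusted p = 0.00149 with an estimated correlation).

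Mitotic genes fell at 2 h in 32 of 34 cases (34 adjusted over the list alone, median -0.61). Plk1 fell by 1.65 ± 0.09 and Cdc20 by 1.25 ± 0.093, but the camera call (adjusted p = 4.61e-16) was lost, at adjusted p = 0.211 with an estimated correlation. Of the Hox genes 17 of 27 fell and 1, Hoxa5 (0.27 ± 0.089), rose (camera adjusted p = 1.38e-06, and adjusted p = 0.007 with an estimated correlation). BMP targets rose in 12 of 19 cases and fell in 4 (13 and 4 adjusted over the list alone, camera adjusted p = 1.55e-05, and adjusted p = 0.0125 with an estimated correlation). Smad7 rose by 1.68 ± 0.068 and Bambi, a decoy receptor gene, by 1.29 ± 0.073. Inflammatory and NF-kB targets were raised (16 of 28 higher, 2 lower, camera adjusted p = 1.97e-09, and adjusted p = 0.000494 with an estimated correlation). So were heat shock and oxidative stress genes (13 of 20 higher, 2 lower, camera adjusted p = 5.5e-11, and adjusted p = 0.0254 with an estimated correlation). Lcn2 rose by 2.94 ± 0.094, Gclc by 3.08 ± 0.074 and Bag3 by 2.21 ± 0.062. The early adipogenic transcription factors split into 8 higher and 8 lower, and their median (-0.05) and mean (0.66) had opposite signs (camera adjusted p = 0.0277, and adjusted p = 0.543 with an estimated correlation, direction up). In that list Klf5 rose by 2.92 ± 0.094, and the adipogenesis repressor gene Klf3 fell by 1.33 ± 0.071.

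At 4 h ribosome biogenesis genes had risen throughout the list. All 26 measured members were higher, also when adjusted over the list alone (median 1.46, camera adjusted p = 3e-22, and adjusted p = 0.0282 with an estimated correlation), among them Rrs1 (2.20 ± 0.183), Rrp12 (2.07 ± 0.07), Rrp9 (2.00 ± 0.071) and Polr1b, which encodes a subunit of RNA polymerase I (1.94 ± 0.094). Tcim (5.42 ± 0.108), Fgl2 (5.06 ± 0.125), Prg4, the lubricin gene (4.85 ± 0.113), Lcn2 (4.49 ± 0.094) and the receptor modifier gene Ramp3 (3.98 ± 0.111) were among the largest rises. Bmp4 was now the largest fall (-3.55 ± 0.104, adjusted p = 1.85e-19), followed by Cdc42ep3 (-3.35 ± 0.12) and Trim30d (-3.25 ± 0.164). The iron exporter gene Slc40a1 (-3.03 ± 0.101) was also among the largest falls. Isl1 stood 0.95 ± 0.107 above 0 h and Cebpb 2.34 ± 0.086, Cebpa fell by 0.28 ± 0.101, and Pparg (0.03 ± 0.06) did not pass the test.

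Glucocorticoid targets at 4 h had 18 higher and 2 lower of 28 (median 1.28, camera adjusted p = 1.58e-12, and adjusted p = 0.00424 with an estimated correlation). Fkbp5 rose by 3.79 ± 0.068 and Glul, which encodes glutamine synthetase, by 3.23 ± 0.067. The cAMP targets stayed up (20 of 29 higher, 5 lower, median 1.28, camera adjusted p = 3.93e-11, and adjusted p = 0.0178 with an estimated correlation). Immediate early genes did too (26 of 29 higher, 2 lower, median 1.51, camera adjusted p = 5.79e-19, and adjusted p = 0.0125 with an estimated correlation). Nr4a3 rose by 3.38 ± 0.116 and Nr4a1 by 4.11 ± 0.064. Hox genes fell in 17 of 27 cases (camera adjusted p = 3.65e-05, and adjusted p = 0.0178 with an estimated correlation). Hoxd4 fell by 1.39 ± 0.084. Cholesterol synthesis genes fell in 17 of 20 cases and rose in 2 (18 and 2 adjusted over the list alone, median -0.60, camera adjusted p = 1.42e-05, and adjusted p = 0.376 with an estimated correlation). Fdft1 fell by 1.59 ± 0.085 and Pmvk rose by 2.75 ± 0.077. Interferon response genes were lower in 18 of 28 and higher in 2 (median -0.57, camera adjusted p = 0.000131, and adjusted p = 0.324 with an estimated correlation). Ifit3 fell by 3.05 ± 0.2. DNA replication genes were lower in 24 of 34 and higher in 5 (camera adjusted p = 0.000157, and adjusted p = 0.547 with an estimated correlation). Mitotic genes were lower in 32 of 34 (camera adjusted p = 8.75e-12, and adjusted p = 0.315 with an estimated correlation). Mki67 fell by 1.11 ± 0.09.

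At 8 h Lcn2, the lipocalin gene, had risen by 5.23 ± 0.094, Prg4 by 4.93 ± 0.113, Ramp3 by 4.60 ± 0.111, Fgl2 by 4.45 ± 0.125 and the acute phase gene Serpina3n by 4.08 ± 0.09. Among the largest falls were Akr1c14 (-4.58 ± 0.143), Sorbs2 (-4.38 ± 0.096), Bmp4 (-4.07 ± 0.104, adjusted p = 9.79e-21), Ifit3 (-3.84 ± 0.2) and Rerg (-3.51 ± 0.082). Ribosome biogenesis genes stayed higher in all 26 cases (median 1.62, camera adjusted p = 3.25e-21, and adjusted p = 0.0312 with an estimated correlation). Ddx21 rose by 2.11 ± 0.091 and Polr1b by 2.05 ± 0.094. Glucocorticoid targets kept their direction (18 of 28 higher, 6 lower, median 0.75, camera adjusted p = 2.68e-06, and adjusted p = 0.0362 with an estimated correlation). So did Hox genes (14 of 27 lower, median -0.27, camera adjusted p = 0.000768, and adjusted p = 0.0429 with an estimated correlation). Fkbp5 rose by 3.38 ± 0.068, and Hoxd4 fell by 1.19 ± 0.084. Matrix and cytoskeleton genes were lower in 26 of 37 and higher in 7 (median -0.37, camera adjusted p = 1.92e-05, and adjusted p = 0.146 with an estimated correlation). TGF-beta targets were lower in 11 of 17 with 3 higher (median -0.42, camera adjusted p = 0.00474, and adjusted p = 0.324 with an estimated correlation). Tpm1 fell by 1.63 ± 0.054, Myl9 by 1.56 ± 0.078, Tagln by 1.29 ± 0.111 and the thrombospondin genes Thbs1 and Thbs2 by 1.18 ± 0.062 and 1.28 ± 0.064, while the basement membrane gene Col4a1 rose by 1.27 ± 0.078. The preadipocyte growth factor receptor genes Pdgfra and Pdgfrb fell by 1.43 ± 0.06 and 1.72 ± 0.073. Cholesterol synthesis genes stayed low (17 of 20 lower, camera adjusted p = 5.44e-06, and adjusted p = 0.346 with an estimated correlation). Interferon genes stayed low as well (18 of 28 lower, camera adjusted p = 3.44e-06, and adjusted p = 0.211 with an estimated correlation). Adipocyte markers had 8 higher and 15 lower of 30, with no camera call (camera adjusted p = 0.186, and adjusted p = 0.807 with an estimated correlation), and Pparg had fallen by 0.17 ± 0.06.

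**Figure D3:**
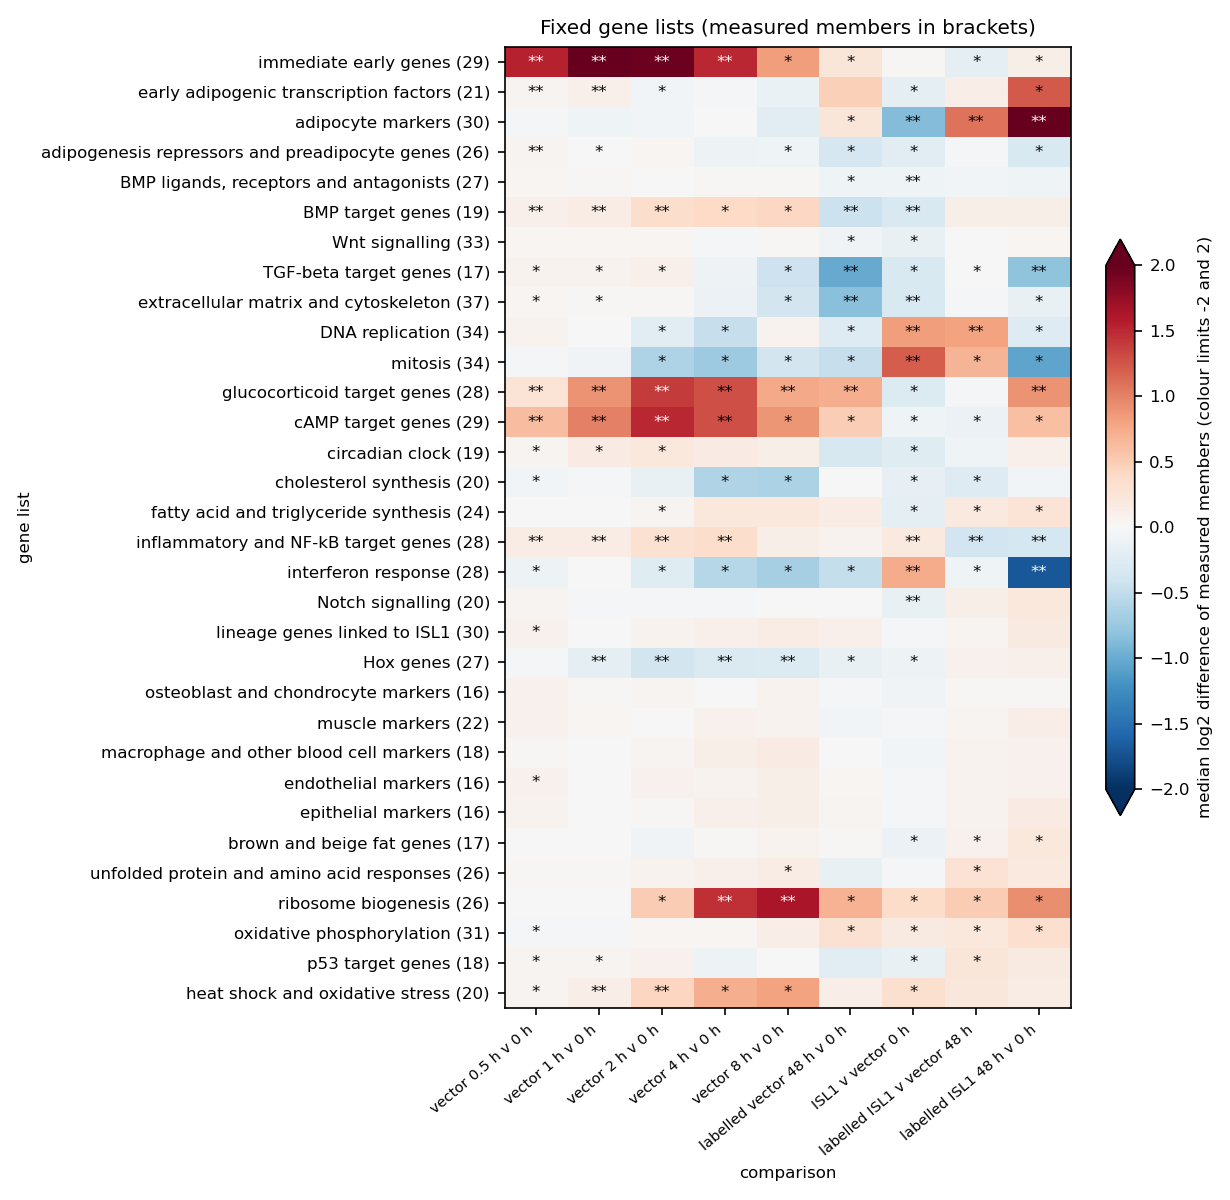
Median log2 difference of the measured members of each of the 32 fixed gene lists (one line per list, number measured in brackets) in 9 comparisons (columns), in colour from -2 to 2. One star marks a camera call at the preset correlation and a pair of stars a call that also held with an estimated correlation; ribosome biogenesis reached 1.46 at 4 h and 1.62 at 8 h.

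In the arrays labelled vector 48 h, against vector 0 h, 7342 genes passed (3609 higher, 3733 lower; 426 and 568 with at least a 2-fold change). Isl1 itself was 5.42 ± 0.107 higher (adjusted p = 4.85e-23), so all directions here are those of the labels and not of a settled construct. The lipase family gene Lipi stood 6.86 ± 0.075 higher, Prg4 6.77 ± 0.113, Lcn2 5.80 ± 0.094, the B cell chemokine gene Cxcl13 5.60 ± 0.135 and the acute phase gene Saa3 4.63 ± 0.125. Lyz2 fell by 5.30 ± 0.087, Timp3, which encodes a metalloproteinase inhibitor, by 5.27 ± 0.082 and Bmp4 by 4.30 ± 0.104. The imprinted growth genes Igf2 (-4.52 ± 0.079) and Grb10 (-4.38 ± 0.078) fell too. Pparg rose by 0.83 ± 0.06 and Cebpd by 1.22 ± 0.086, Cebpa (0.11 ± 0.101) did not pass, and the adipokine gene Adipoq fell by 3.53 ± 0.113. Matrix and cytoskeleton genes fell in 28 of 37 cases and rose in 5 (29 and 5 adjusted over the list alone, median -0.83, camera adjusted p = 4.61e-16, and adjusted p = 0.0079 with an estimated correlation). Myl9 fell by 3.33 ± 0.078 and Col12a1 by 3.27 ± 0.085. TGF-beta targets fell in 15 of 17 cases with 1, Tgfbi (1.21 ± 0.076), higher (camera adjusted p = 2.27e-11, and adjusted p = 0.0155 with an estimated correlation). BMP targets fell in 12 of 19 with 2 higher (camera adjusted p = 0.000243, and adjusted p = 0.0274 with an estimated correlation). Glucocorticoid targets rose in 17 of 28 cases and fell in 4 (camera adjusted p = 3.42e-09, and adjusted p = 0.0128 with an estimated correlation). Fkbp5 rose by 3.52 ± 0.068 and Zbtb16 by 2.91 ± 0.092. Adipocyte markers had 16 higher and 8 lower of 30 (median 0.25, camera adjusted p = 0.0484, and adjusted p = 0.692 with an estimated correlation). With the 48 h labels exchanged, 8248 genes passed (4251 higher, 3997 lower), Isl1 stood 0.32 ± 0.107 above vector 0 h, and 25 of the adipocyte markers were higher and 1 lower (median 1.34), a call that then held with an estimated correlation (adjusted p = 0.0356). The BMP targets then had 6 higher and 10 lower, and their call (camera adjusted p = 0.0301) was lost with an estimated correlation (adjusted p = 0.164). Several gene changes also depend on the labels. In the arrays labelled ISL1 48 h the mean levels were 11.22 for Cebpa, 13.06 for Pparg, 10.84 for Adipoq, 5.24 for Lipi and 7.71 for Bmp4. At vector 0 h they were 9.12, 11.78, 10.76, 5.34 and 11.77, so of these Bmp4 was clearly lower under either labelling.

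Successive times were also compared in vector cells. From 0.5 to 1 h 718 genes passed (366 higher, 352 lower), with rises in Nr4a3 (3.23 ± 0.116), Pfkfb3, a regulator gene of glycolysis (2.24 ± 0.081), Nr4a2 (2.06 ± 0.088) and Fkbp5 (1.58 ± 0.068). The largest falls were in Mir145a (-1.80 ± 0.115), Zfp763 (-1.18 ± 0.186) and Ppp1r3c (-1.14 ± 0.109). Median centring moved the share of higher genes from 51% to 72.1% of the calls in this step, and the array spread as a covariate, an alternative chosen after seeing the data, moved it to 37.6%. Immediate early genes rose further (19 of 29 higher, camera adjusted p = 2.4e-50, and adjusted p = 0.000158 with an estimated correlation). So did 15 of 28 glucocorticoid targets (camera adjusted p = 1.02e-31, and adjusted p = 2.7e-05 with an estimated correlation). Heat shock and oxidative stress genes rose in 8 of 20 (camera adjusted p = 3.21e-17, and adjusted p = 0.00654 with an estimated correlation). The TGF-beta targets were called up (camera adjusted p = 0.0153, and adjusted p = 0.419 with an estimated correlation) at a mean of 0.095 and a median of -0.021. The fatty acid and triglyceride genes were called likewise (camera adjusted p = 0.0395, and adjusted p = 0.639 with an estimated correlation) at 0.058 and -0.026.

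From 1 to 2 h 4133 genes passed (1888 higher, 2245 lower). Fgl2 rose by 2.88 ± 0.125, Gfpt2 by 2.84 ± 0.093, Prg4 by 2.63 ± 0.113 and Isl1 by 1.11 ± 0.107, while Cdc42ep3 fell by 2.42 ± 0.12, Btg2 by 2.35 ± 0.096, Fos by 2.29 ± 0.103, Irs1 by 2.01 ± 0.085 and Bmp4 by 1.91 ± 0.104. Hox genes fell in 12 of 27 cases (camera adjusted p = 1.69e-05, and adjusted p = 0.0139 with an estimated correlation). Hoxa2 fell by 0.71 ± 0.071. Mitotic genes fell in 26 of 34 (camera adjusted p = 2.43e-20, and adjusted p = 0.143 with an estimated correlation). Ribosome biogenesis genes rose in 20 of 26 (camera adjusted p = 2.2e-17, and adjusted p = 0.0579 with an estimated correlation). For Irf1, which fell by 1.19 ± 0.106, the probe set with the weaker signal gave 0.014, and for its falls at 1 h and 2 h against 0 h it gave -0.087 and -0.073. For Irs1 the weaker probe set gave -0.298 in this step and -0.397 at 2 h against 0 h.

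From 2 to 4 h 5579 genes passed (2740 higher, 2839 lower). The largest rises were in the adhesion gene Ceacam1 (2.35 ± 0.135), Arl14epl (2.14 ± 0.083) and Serpina3n (1.88 ± 0.09). The largest falls were in the vasodilator peptide gene Adm (-2.21 ± 0.114), Trim30d (-2.05 ± 0.164) and Nr4a3 (-2.04 ± 0.116). Immediate early genes came down in 21 of 29 cases with 4 higher (camera adjusted p = 1.62e-12, and adjusted p = 0.0362 with an estimated correlation). Ribosome biogenesis genes rose in all 26 (camera adjusted p = 7.67e-25, and adjusted p = 0.0236 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 20 cases (camera adjusted p = 1.87e-08, and adjusted p = 0.221 with an estimated correlation), and Bmp4 fell by a further step (-1.50 ± 0.104).

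From 4 to 8 h 4767 genes passed (2725 higher, 2042 lower), and median centring moved the higher share from 57.2% to 44%. Akr1c14 fell by 2.95 ± 0.143, Sorbs2 by 2.57 ± 0.096 and the polarity gene Mpp7 by 2.49 ± 0.085, and H2-M1 (1.62 ± 0.133), Mrgprf (1.53 ± 0.092) and Ints3 (1.43 ± 0.076) rose. Immediate early genes fell in 23 of 29 cases (camera adjusted p = 1.49e-21, and adjusted p = 0.00774 with an estimated correlation). Matrix and cytoskeleton genes fell in 20 of 37 (camera adjusted p = 5.31e-12, and adjusted p = 0.0213 with an estimated correlation). So did 12 of 17 TGF-beta targets (camera adjusted p = 2.3e-09, and adjusted p = 0.0264 with an estimated correlation). Glucocorticoid targets fell in 15 of 28 (camera adjusted p = 1.54e-07, and adjusted p = 0.0238 with an estimated correlation). Of the cAMP targets 18 of 29 fell (camera adjusted p = 6.62e-09, and adjusted p = 0.0312 with an estimated correlation). DNA replication genes rose in 21 of 34 cases and fell in 1 (camera adjusted p = 7.43e-10, and adjusted p = 0.263 with an estimated correlation). Rfc3 rose by 1.22 ± 0.101 and Mcm6 by 0.93 ± 0.086.

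Against vector 8 h, the arrays labelled vector 48 h had 7310 genes past the test (3543 higher, 3767 lower), with Isl1 4.74 ± 0.107 higher, so directions are again as labelled. Lipi (6.87 ± 0.075), Ang5 (5.14 ± 0.143), the angiotensin receptor gene Agtr2 (5.02 ± 0.106) and Cxcl13 (4.94 ± 0.135) were higher. The largest falls were in Gm10747 (-5.35 ± 0.13), Fgl2 (-4.84 ± 0.125) and Timp3 (-4.81 ± 0.082). BMP targets fell in 15 of 19 cases (camera adjusted p = 9.61e-09, and adjusted p = 0.00156 with an estimated correlation). Smad7 fell by 1.85 ± 0.068 and Id1 by 1.42 ± 0.085. Matrix and cytoskeleton genes fell in 24 of 37 (camera adjusted p = 1.73e-10, and adjusted p = 0.0282 with an estimated correlation). Pparg rose by 1.01 ± 0.06, and cholesterol synthesis genes rose in 15 of 20 cases (camera adjusted p = 5.04e-08, and adjusted p = 0.236 with an estimated correlation). With the labels exchanged, 6105 genes passed (3132 higher, 2973 lower).

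ISL1 and vector cells at 0 h were compared to ask how they differed before induction. The arrays of a construct may come from 1 transduced line. An effect of ISL1 could then not be told apart from other differences between the lines, here or at 48 h. Isl1 was 5.29 ± 0.107 higher in ISL1 cells (39-fold, adjusted p = 1.49e-22). Adipocyte genes were lower: Adipoq fell by 4.20 ± 0.113, Cd36, a fatty acid transporter gene, by 3.45 ± 0.158 and Gpd1, which supplies glycerol phosphate for triglycerides, by 3.77 ± 0.095. The fatty acid binding protein gene Fabp4 (-3.15 ± 0.085) and the carbonic anhydrase gene Car3 (-3.89 ± 0.137) fell as well. Pparg fell by 0.38 ± 0.06 (adjusted p = 1.74e-05), Cebpa by 1.14 ± 0.101 and Cebpd by 0.77 ± 0.086, while Cebpb (0.00 ± 0.086) did not pass. Of the adipocyte markers 25 of 30 were lower and 2 higher (25 and 3 adjusted over the list alone, median -0.87, camera adjusted p = 9.3e-24, and adjusted p = 0.0115 with an estimated correlation). In all 5119 genes passed (3047 higher, 2072 lower; 296 and 211 with at least a 2-fold change). Quantile normalization again gave 3014 higher and 2909 lower, which moved the higher share from 59.5% to 50.9%.

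Bmp4 fell by 3.55 ± 0.104 in ISL1 cells at 0 h (adjusted p = 2.51e-19), a level 11.7-fold below that of vector cells. Of the BMP ligands, receptors and antagonists 9 of 27 fell and 1, the antagonist gene Grem1 (0.72 ± 0.069), rose (the same adjusted over the list alone, median -0.09, camera adjusted p = 0.000663, and adjusted p = 0.0238 with an estimated correlation), with the antagonist gene Chrdl1 down (it fell by 3.79 ± 0.084). BMP targets fell in 10 of 19 cases and rose in 1 (the same adjusted over the list alone, median -0.30, camera adjusted p = 1.45e-06, and adjusted p = 0.00674 with an estimated correlation). Id2 fell by 0.77 ± 0.071 and Hey1 by 1.15 ± 0.103. Matrix and cytoskeleton genes fell in 27 of 37 cases and rose in 3 (29 and 4 adjusted over the list alone, median -0.30, camera adjusted p = 1.11e-12, and adjusted p = 0.0178 with an estimated correlation), among them Lum (-3.89 ± 0.127), Col12a1 (-2.48 ± 0.085) and Timp3 (-2.06 ± 0.082). Notch genes fell in 6 of 20 cases with 1 higher (camera adjusted p = 0.000375, and adjusted p = 0.0278 with an estimated correlation), including Hes1 (-1.10 ± 0.09). The Wnt list (13 of 33 lower, 4 higher, camera adjusted p = 0.000534, and adjusted p = 0.143 with an estimated correlation) lost its call with an estimated correlation; Rspo3, a Wnt agonist gene, rose by 2.07 ± 0.104 and the receptor gene Fzd4 fell by 1.23 ± 0.092.

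Proliferation and interferon genes were higher in ISL1 cells at 0 h. All 34 mitotic genes rose (also adjusted over the list alone, median 1.22, camera adjusted p = 7.69e-41, and adjusted p = 0.0285 with an estimated correlation). Hmmr rose by 1.53 ± 0.137, Ect2 by 1.52 ± 0.137 and Ttk by 1.48 ± 0.124. DNA replication genes rose in 33 of 34 cases (also adjusted over the list alone, median 0.83, camera adjusted p = 7.42e-28, and adjusted p = 0.0312 with an estimated correlation). Prim1 rose by 1.47 ± 0.137 and Tk1 by 1.28 ± 0.08. Interferon response genes rose in 23 of 28 cases (25 adjusted over the list alone, median 0.75, camera adjusted p = 3.97e-15, and adjusted p = 0.0282 with an estimated correlation). Rtp4 rose by 2.18 ± 0.162, Usp18 by 2.15 ± 0.227 and Oasl2 by 1.84 ± 0.219. Inflammatory and NF-kB targets had 14 higher and 6 lower of 28 (the same adjusted over the list alone, camera adjusted p = 0.00171, and adjusted p = 0.0362 with an estimated correlation), with the monocyte chemokine genes Ccl2 and Ccl7 at 1.73 ± 0.1 and 1.34 ± 0.081. The largest rises besides Isl1 were in Lipi (6.57 ± 0.075), the relaxin receptor gene Rxfp1 (6.17 ± 0.086), AW551984 (4.99 ± 0.101), Lrrn3 (3.38 ± 0.092), the ephrin receptor gene Epha6 (3.15 ± 0.088), the adhesion gene Chl1 (3.13 ± 0.104) and Agtr2 (3.10 ± 0.106). Among the largest falls were Lyz2 (-4.84 ± 0.087), Gm10747 (-4.36 ± 0.13), Grb10 (-4.22 ± 0.078), Lrrc10 (-4.04 ± 0.103), Rab12 (-3.99 ± 0.098) and Igf2 (-3.79 ± 0.079). Of the lineage genes linked to ISL1 in motor neurons, heart and pancreas, 1, the acetylcholine synthesis transporter gene Slc5a7 (1.53 ± 0.1), rose and 2, Ldb1 (-0.31 ± 0.05) and Slit2 (-1.11 ± 0.068), fell, of 30, with no camera call (camera adjusted p = 0.609, and adjusted p = 0.948 with an estimated correlation). The macrophage and other blood cell markers had 1 higher, Cd74 (0.60 ± 0.092), and 4 lower of 18, Lyz2 among them, also with no camera call (camera adjusted p = 0.052, and adjusted p = 0.396 with an estimated correlation).

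Several of the genes that were lower in ISL1 cells at 0 h lie side by side on chromosome 10 in the gene order of the GRCm38.p6 annotation, used here for names and order only. Over 17 neighbouring genes from Rab3ip to Mdm1, 12 were at least 2-fold lower past the test, among them Rab3ip (-2.57 ± 0.073), Gm10747, Lrrc10, Lyz2, Yeats4 (-2.21 ± 0.075) and Nup107 (-1.25 ± 0.076). Mdm2 (0.16 ± 0.054, adjusted p = 0.0277) and Slc35e3 (0.46 ± 0.083, adjusted p = 0.000113), which lie between them, were higher. The run was chosen after its values were seen, as were the genes named from it.

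**Figure D4:**
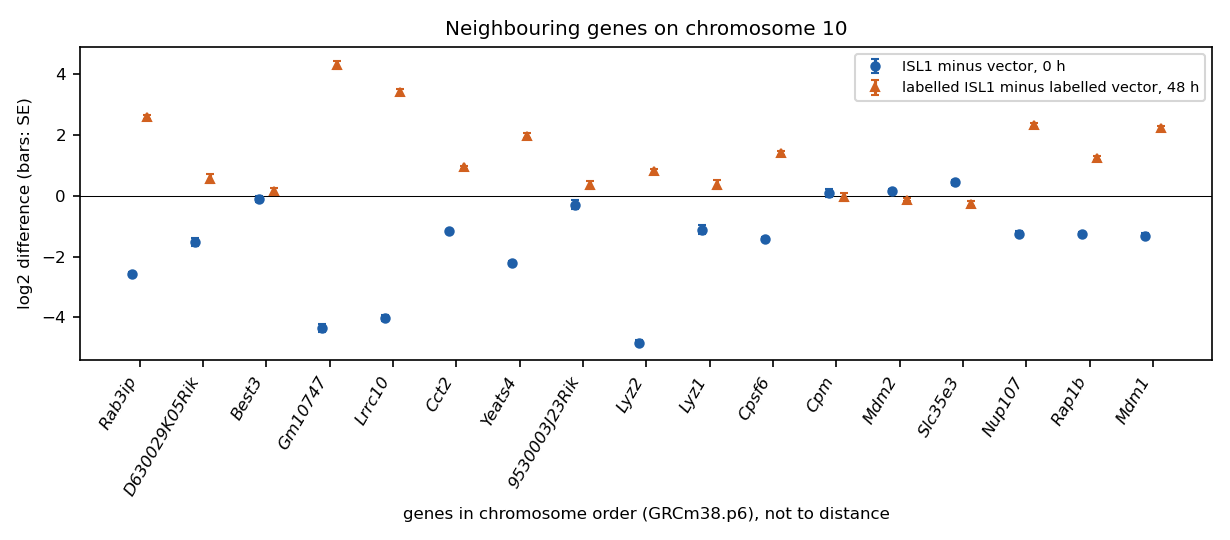
Log2 difference with its standard error for 17 neighbouring genes on chromosome 10, in chromosome order, between ISL1 and vector at 0 h (circles) and between the arrays labelled ISL1 and vector at 48 h (triangles). The 14 genes above the median level had a median of -1.37 at 0 h and 1.32 at 48 h as labelled.

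At 48 h the arrays labelled ISL1 and vector were compared to ask how they differed once differentiation was under way. Isl1 was lower in the arrays labelled ISL1 (it fell by 5.11 ± 0.107, adjusted p = 5.22e-22), so the directions that follow are as labelled and turn if the labels were exchanged. In these arrays Adipoq was 3.61 ± 0.113 higher, Gpd1 3.35 ± 0.095, the triglyceride synthesis gene Dgat2 3.24 ± 0.117, the lipid droplet gene Cidec 2.84 ± 0.105, Cebpa 1.98 ± 0.101 and Pparg 0.45 ± 0.06 (adjusted p = 1.32e-06). Bmp4 (0.23 ± 0.104) and Cebpb (-0.12 ± 0.086) did not pass, and Cebpd fell by 0.35 ± 0.086. Of the adipocyte markers 25 of 30 were higher and 2 lower (the same adjusted over the list alone, median 1.08, camera adjusted p = 2.06e-20, and adjusted p = 0.0178 with an estimated correlation). DNA replication genes were higher in 32 of 34 cases (33 adjusted over the list alone, median 0.81, camera adjusted p = 1.82e-24, and adjusted p = 0.0461 with an estimated correlation). Rrm2 rose by 1.68 ± 0.075 and Ccne2 by 1.47 ± 0.129. Mitotic genes were higher in 32 of 34 (camera adjusted p = 5.45e-17, and adjusted p = 0.191 with an estimated correlation). Both of these lists were also higher in the ISL1 arrays at 0 h, unlike Isl1, which changed sign. Inflammatory and NF-kB targets were lower in 18 of 28 cases and higher in 1 (19 and 2 adjusted over the list alone, median -0.38, camera adjusted p = 8.09e-09, and adjusted p = 0.000694 with an estimated correlation). Saa3 fell by 2.29 ± 0.125, Vcam1 by 1.09 ± 0.056 and Csf1 by 1.00 ± 0.068.

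Lipi (-6.95 ± 0.075), the interleukin antagonist gene Il1rn (-4.50 ± 0.1), AW551984 (-4.02 ± 0.101), Rxfp1 (-3.86 ± 0.086), Epha6 (-3.75 ± 0.088) and Chl1 (-3.27 ± 0.104) were, with Isl1, among the largest falls in the arrays labelled ISL1 at 48 h. Gm10747 (4.31 ± 0.13), Grb10 (4.01 ± 0.078), Igf2 (3.95 ± 0.079), Rab12 (3.51 ± 0.098) and Lrrc10 (3.43 ± 0.103) were among the largest rises there. Unfolded protein and amino acid response genes were higher in 19 of 26 cases and lower in 1 (camera adjusted p = 1.8e-07, and adjusted p = 0.16 with an estimated correlation), with the transporter gene Slc7a5 at 1.68 ± 0.068 and Chac1 at 1.24 ± 0.113. Brown and beige fat genes were higher in 5 of 17 cases (camera adjusted p = 0.0187, and adjusted p = 0.288 with an estimated correlation), among them the coactivator gene Ppargc1a (1.93 ± 0.103) and Elovl3 (2.08 ± 0.122). Ribosome biogenesis genes were higher in 22 of 26 (camera adjusted p = 7.92e-13, and adjusted p = 0.111 with an estimated correlation). In all 5553 genes passed as labelled (2793 higher, 2760 lower; 179 and 240 with at least a 2-fold change), and exchanging the labels gives the same 5553 with 2760 higher and 2793 lower.

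**Figure D5:**
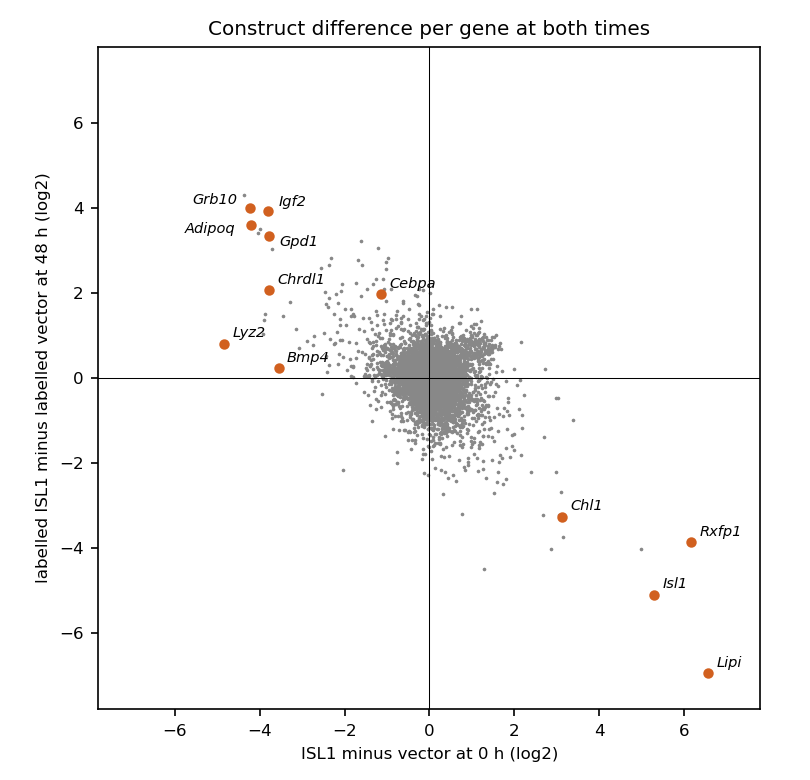
Log2 difference of each of 19938 genes between ISL1 and vector at 0 h (horizontal axis) and between the arrays labelled ISL1 and vector at 48 h (vertical axis), with 12 genes named. Isl1 and Lipi lie in the lower right and Adipoq, Gpd1, Grb10 and Igf2 in the upper left; across genes r was -0.31.

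The arrays labelled ISL1 48 h were set against ISL1 0 h for the response to the mixture in ISL1 cells. Isl1 fell by 4.97 ± 0.107 (adjusted p = 1.74e-22), against the label, so the directions are again as labelled. Adipocyte genes rose. Cd36 rose by 4.75 ± 0.158, Fabp4 by 4.73 ± 0.085, Retn, the resistin gene, by 4.60 ± 0.103, Cidec by 4.48 ± 0.105, Dgat2 by 4.42 ± 0.117, Cebpa by 3.24 ± 0.101 and Pparg by 1.67 ± 0.06. Of the adipocyte markers 27 of 30 rose and 1 fell (the same adjusted over the list alone, median 2.18, camera adjusted p = 5.46e-27, and adjusted p = 0.00732 with an estimated correlation). Lcn2 (5.95 ± 0.094), the melanocortin receptor gene Mc5r (5.09 ± 0.106), Cxcl13 (4.97 ± 0.135), Serpina3n (4.86 ± 0.09) and Prg4 (4.67 ± 0.113) were among the largest rises. Interferon response genes fell in 25 of 28 cases (median -1.70, camera adjusted p = 1.76e-16, and adjusted p = 0.0238 with an estimated correlation). Ifit3 fell by 4.60 ± 0.2 and Oasl2 by 4.01 ± 0.219. TGF-beta targets fell in 13 of 17 cases (camera adjusted p = 5.77e-09, and adjusted p = 0.0282 with an estimated correlation), with Acta2 and Tagln, which encode contractile proteins, down (they fell by 3.34 ± 0.067 and 2.37 ± 0.111). Inflammatory and NF-kB targets had 6 higher and 15 lower of 28 (camera adjusted p = 0.000466, and adjusted p = 0.0238 with an estimated correlation). Ccl2 fell by 3.93 ± 0.1 and Ccl7 by 3.13 ± 0.081. Glucocorticoid targets rose in 22 of 28 cases and fell in 2 (camera adjusted p = 7.23e-12, and adjusted p = 0.00529 with an estimated correlation). Glul rose by 3.95 ± 0.067 and Zbtb16 by 3.15 ± 0.092. All 34 mitotic genes fell (camera adjusted p = 2e-19, and adjusted p = 0.151 with an estimated correlation). As labelled 8590 genes passed (4166 higher, 4424 lower; 491 and 886 with at least a 2-fold change), and with the labels exchanged 6619 (2823 higher, 3796 lower), with all 34 mitotic genes again lower (median -1.70), a call that then held with an estimated correlation (adjusted p = 0.0369). So did that of DNA replication, with 33 of 34 lower (adjusted p = 0.0381). The inflammatory and NF-kB targets then had 7 higher and 12 lower, without a camera call (adjusted p = 0.112). Of the adipocyte markers 27 were then higher and 0 lower, but at a median of 0.985 in place of 2.18 (adjusted p = 0.0166 with an estimated correlation). The size of the rise in adipocyte genes thus depends on the labels. Cebpa was 7.98 at ISL1 0 h, 11.22 in the arrays labelled ISL1 48 h and 9.24 in those labelled vector 48 h. For Fabp4 these means were 8.23, 12.97 and 11.82.

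The difference between the construct's effect at 48 h as labelled and at 0 h was tested for each gene. Isl1 had a difference of -10.39 ± 0.152 and Lipi of -13.52 ± 0.106. Rxfp1 (-10.03 ± 0.122), AW551984 (-9.01 ± 0.142) and Epha6 (-6.89 ± 0.124) were also negative. The mean level of Lipi was 5.335 at vector 0 h and 5.243 in the arrays labelled ISL1 48 h, below the lower quartile of the arrays, and whether it exceeded background there was not tested. Adipocyte genes were among those with positive differences. Adipoq stood at 7.81 ± 0.159, Gpd1 at 7.13 ± 0.134, Cidec at 5.16 ± 0.149 and Cd36 at 4.92 ± 0.224. Bmp4 (3.78 ± 0.147), Cebpa (3.12 ± 0.143), Pparg (0.83 ± 0.085) and Cebpd (0.42 ± 0.122) were positive, and Cebpb (-0.13 ± 0.121) did not pass. Of the adipocyte markers 27 of 30 had a positive and 2 a negative difference (the same adjusted over the list alone, median 1.91, camera adjusted p = 1.73e-30, and adjusted p = 0.005 with an estimated correlation). Inflammatory and NF-kB targets were negative in 16 of 28 cases (median -0.58, camera adjusted p = 2.63e-09, and adjusted p = 0.000511 with an estimated correlation). Ccl2 stood at -2.62 ± 0.141, Nfkbie at -2.17 ± 0.108 and Ccl5 at -2.08 ± 0.131. Interferon genes were negative in 21 of 28 (camera adjusted p = 1.35e-11, and adjusted p = 0.0609 with an estimated correlation). Mitotic genes were negative in 26 of 34 (camera adjusted p = 7.2e-10, and adjusted p = 0.376 with an estimated correlation). In all 5778 genes passed (2532 positive, 3246 negative), and with the labels exchanged 4888 (2266 positive, 2622 negative). Under the exchanged labels the difference of Isl1 was -0.18 ± 0.152 and did not pass (adjusted p = 0.502). The adipocyte markers then had 11 positive and 9 negative (median -0.08, camera adjusted p = 0.847). The inflammatory and NF-kB targets had 9 positive and 7 negative (camera adjusted p = 0.29). All 34 DNA replication genes (median -1.65) and all 34 mitotic genes (median -1.93) were negative, with adjusted p = 0.0166 and 0.0198 with an estimated correlation. Ribosome biogenesis was negative in 25 cases (adjusted p = 0.0327 with an estimated correlation). Positive lists called in this way were BMP ligands, receptors and antagonists (14 positive, none negative, adjusted p = 0.00735), TGF-beta targets (13 positive, none negative, adjusted p = 0.0168) and matrix and cytoskeleton (25 positive, 2 negative, adjusted p = 0.0168).

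Effects that share a group were set beside simulations of noise without effects. Of the genes past the test in both ISL1 comparisons, 1184 had the same sign at both times, against 714 for independent lists, and 1613 the opposite sign, against 712. Across 19938 genes, which are not independent replicates, the effects at 0 h and at 48 h as labelled had r = -0.31 (rho = -0.13, covariance -0.04) against a simulated value without effects of 3e-04. The effect at 48 h and the response of the arrays labelled vector share those arrays: r was -0.29 against a simulated -0.50, with covariances of -0.052 and -0.0047. For the effect at 48 h and the response of the arrays labelled ISL1, r was 0.56 against 0.50 (covariances 0.117 and 0.0047). For the effect at 0 h and the response of the arrays labelled vector it was 0.43 against 0.50 (covariances 0.0797 and 0.0047).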

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

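The tests of the label pattern in this part were chosen only after the result was seen. The test of the difference between the construct's effects at 48 h and 0 h, and the splits of the arrays, were planned.

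The results in this paragraph stood out because the effect of the construct at 48 h, as labelled, differed from that at 0 h by the test of the difference itself. It passed for 5778 genes. The differences, 48 h minus 0 h in log2 units, were -10.39 for Isl1, 3.78 for Bmp4, 0.83 for Pparg, 3.12 for Cebpa and 0.42 for Cebpd. The most positive were Gm10747 (8.67), Grb10 (8.23), Adipoq (7.81), Igf2 (7.74), Rab12 (7.50), Lrrc10 (7.46), Gpd1 (7.13), Lgals12 (6.74), Chrdl1 (5.85) and Lyz2 (5.65). Among the most negative besides Isl1 were Lipi (-13.52), Rxfp1 (-10.03), AW551984 (-9.01), Epha6 (-6.89), 2610528A11Rik (-6.88), Chl1 (-6.40), Lrrc4c (-6.28), Npy1r (-5.92) and Agtr2 (-5.79).

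Gene lists whose members differed between the times on the whole had these median differences. Positive were early adipogenic transcription factors (0.43), adipocyte markers (1.91), BMP targets (0.24), matrix and cytoskeleton (0.16), glucocorticoid targets (0.24), fatty acid and triglyceride synthesis (0.54). Also positive were Notch signalling (0.21), Hox genes (0.20), brown and beige fat genes (0.22), unfolded protein and amino acid responses (0.29) and p53 targets (0.40). Negative were mitosis (-0.58), inflammatory and NF-kB targets (-0.58) and interferon response (-0.96). With an estimated correlation only adipocyte markers (adjusted p = 0.005) and inflammatory and NF-kB targets (adjusted p = 0.000511) were still called, and interferon response had adjusted p = 0.0609. With the 48 h labels exchanged neither of the 2 was called (camera adjusted p = 0.847 and 0.29). The fatty acid, Hox, brown and beige fat and p53 lists lost their calls as well (0.779, 0.293, 0.93 and 0.892), and unfolded protein and amino acid responses turned negative (median -0.21). Called with an estimated correlation were then DNA replication and mitosis, negative in all 34 members each (adjusted p = 0.0166 and 0.0198), and ribosome biogenesis, also negative (adjusted p = 0.0327). Positive in that way were BMP ligands, receptors and antagonists (adjusted p = 0.00735), TGF-beta targets and matrix and cytoskeleton (both 0.0168). In 100 arrangements of the construct labels within each time, the real one included, 1 gave as many genes as the real 5778, itself. The highest other drawn gave 3040. This is the smallest share these draws can give, and it bears only on a random arrangement of the labels. The arrangement with the labels exchanged at 48 h in all arrays was not among those drawn, and it gave 4888.

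The Isl1 values at 48 h go against the labels, and the group labelled vector 48 h lies only 0.135 above the level of ISL1 0 h. An exchange of the construct labels at 48 h is a candidate explanation. Of 506 genes other than Isl1 at least 2-fold apart at 0 h 64.4% had the opposite sign at 48 h (r = -0.591 over these genes). Of the 141 that were 2-fold apart at both times 125, or 88.7%, had the opposite sign. The first share missed the bound first set for it, and the second test was added after that. The tables argue against an exchange at 0 h, since over the 506 genes the vector 0.5 h arrays lay at a median position of 0.009 between vector 0 h (at 0) and ISL1 0 h (at 1). Whether the Isl1 probe set measures the construct's transcript is not known. The tables also argue against a fault of that probe set alone, since 1612 other genes had opposite signs past the test at both times, against 712 for independent lists. Genes of the same sign were in excess too, at 1184 against 714, so an excess is not particular to opposite signs. A loss of Isl1 in ISL1 cells together with a gain in vector cells by 48 h would have to turn many other genes too. Besides the 125 genes above, the 14 genes above the median level in the chromosome 10 run turned. Their median differences were -1.37 at 0 h and 1.32 at 48 h as labelled. An exchange of labels would give such values, but so would genes that follow Isl1. A loss and gain of Isl1 therefore stays open. Under an exchange the effect on the DNA replication genes would have opposite directions at 0 h and 48 h, since they were higher in the arrays labelled ISL1 at both times (medians 0.83 and 0.81). In the vector comparison of 48 h with 0 h, 27 of 34 of these genes were higher and 0 lower under an exchange. As labelled, 2 were higher and 18 lower.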

How the results depend on the processing

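The alternatives with the array spread as a covariate, with the 48 h labels exchanged, with paired arrays and without the 48 h arrays in the F test (10440 genes) were chosen after seeing the data, and the others were planned. Pairing the 48 h arrays, and the vector 0.5, 1 and 4 h arrays, by replicate number gave 6132 genes for ISL1 against vector at 48 h and 6433 for the difference, and ended 4 list calls. Total counts of genes moved by more than 1.5 times only under array weights, the spread covariate and fits of only the arrays compared, and the cause was not tested. Array weights gave 488 genes at 0.5 h, 2850 at 1 h, 1868 from 0.5 to 1 h, 6818 from 1 to 2 h and 8350 from 4 to 8 h. The spread covariate gave 414, 2398 and 1353 for the first 3 of these. Fits of only the arrays compared, which estimate the variance from fewer arrays, gave 912 at 1 h and 398 from 0.5 to 1 h. Counts by direction moved as far under more settings. Median centring changed the lower genes from 856 to 495 at 1 h and from 352 to 138 from 0.5 to 1 h, and the higher ones from 2725 to 1605 from 4 to 8 h. Quantile normalization again changed the lower genes at 0.5 h from 100 to 160. Leaving out an array changed the lower genes to as few as 556 at 1 h and 194 from 0.5 to 1 h. Exchanging the 48 h labels turned the direction of the 5553 genes of that comparison, by its construction, and moved the correlation across genes between the 48 h effect and the vector 48 h response from -0.2865 to -0.4024. Of 219 list calls 72 also held with an estimated correlation, and 198 held on leaving out any 1 array, which moved no total count by more than 1.5 times. Of 1935 called results for named genes 1799 held under all alternatives set before the data were examined in which they were run. The other 136 were lost under some, 119 of them on leaving out an array, and none turned direction. Median centring and fits of only the arrays compared each ended 61 of these calls. Leaving out the 40% dimmest genes ended 22 list calls, and it was run for only 1836 of the 1961 results for named genes, called or not. No other pseudocount was run, as the values are already logarithms. The 48 h, 0 h and 0.5 to 8 h arrays are 3 blocks of sample records, and whether these were batches is not known. The 0 h and 0.5 h arrays, from different blocks, differed in 255 genes, and the steps from 0.5 to 8 h lie within a block. If the 48 h block was a batch, batch and time cannot be told apart there, because it holds no other time.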

Other observations

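The tests on the neighbouring genes of chromosome 10 were chosen only after the result was seen. For the zinc finger genes the list was chosen after seeing the data and its tests were written before their results, and the splits of the arrays were planned.

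Of the clock genes 6 of 19 rose at 1 h and 1 fell (camera adjusted p = 1.09e-07, and adjusted p = 0.14 with an estimated correlation). Per1 rose by 1.96 ± 0.065 and Ciart by 1.22 ± 0.112. At 8 h Dbp had fallen by 2.37 ± 0.086, Per3 by 2.26 ± 0.071 and Nr1d2 by 2.08 ± 0.088. In ISL1 cells at 0 h 10 of 19 fell (camera adjusted p = 1.27e-05, and adjusted p = 0.236 with an estimated correlation). Rora fell by 1.98 ± 0.085 and Nr1d1 by 1.15 ± 0.083. Oxidative phosphorylation genes were higher in 14 of 31 cases in ISL1 cells at 0 h (20 adjusted over the list alone, camera adjusted p = 1.6e-05, and adjusted p = 0.349 with an estimated correlation). They were higher in 22 in the arrays labelled vector 48 h against 0 h (camera adjusted p = 4.48e-07, and adjusted p = 0.254 with an estimated correlation). Of the p53 targets 10 of 18 had a positive and 2 a negative difference of the effect as labelled (camera adjusted p = 0.00503, and adjusted p = 0.328 with an estimated correlation). With the 48 h labels exchanged 3 were positive and 2 negative, without a call (camera adjusted p = 0.892). The fatty acid and triglyceride genes rose in 13 of 24 cases and fell in 7 in the arrays labelled ISL1 48 h against ISL1 0 h (camera adjusted p = 0.005, and adjusted p = 0.482 with an estimated correlation). Heat shock and oxidative stress genes were higher in 13 of 20 cases in ISL1 cells at 0 h (camera adjusted p = 1.16e-05, and adjusted p = 0.134 with an estimated correlation). The chaperone gene Hspb1 fell by 1.28 ± 0.093. Adipogenesis repressors and preadipocyte genes fell in 14 of 26 cases in the arrays labelled vector 48 h (camera adjusted p = 5.36e-05, and adjusted p = 0.0849 with an estimated correlation). With the labels exchanged 17 fell and 3 rose, and the call held with an estimated correlation (adjusted p = 0.0381).

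Muscle (3 of 22 higher, 1 lower, camera adjusted p = 0.481) and epithelial markers (3 of 16 higher, camera adjusted p = 0.129) had no call in the arrays labelled ISL1 48 h against ISL1 0 h. Endothelial markers were called at 0.5 h (camera adjusted p = 0.0325, and adjusted p = 0.579 with an estimated correlation) without a member past the test in limma. At 4 h Flt1 rose by 1.03 ± 0.101 and Cdh5 by 0.65 ± 0.083 with no list call (camera adjusted p = 0.234). Osteoblast and chondrocyte markers had 1 higher, Alpl (2.63 ± 0.083), and 4 lower of 16 at 8 h, with Sox9 down (it fell by 1.21 ± 0.057), and no list call (camera adjusted p = 0.621). Macrophage and other blood cell markers fell in 7 of 18 cases in the arrays labelled vector 48 h against 8 h (camera adjusted p = 0.00497, and adjusted p = 0.189 with an estimated correlation). Lyz2 fell most, by 4.63 ± 0.087. From 0 to 8 h Cd53 rose by 1.95 ± 0.124 and Cd68 by 0.90 ± 0.08.

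A run of neighbouring genes on chromosome 10 was lower in ISL1 cells at 0 h, with 12 genes at least 2-fold lower in a window of 21. Chance positions are argued against, since in 10000 shuffles of the positions of 211 such genes among 19908 no window held more than 6. The permutation p was 1e-04, the smallest these shuffles can give. If RNA followed copy number, 1 copy number difference over the whole run is argued against by 2 genes inside it. These were Mdm2 and Slc35e3, which lay above the median level and were not lower. Without DNA values they cannot exclude it. The prediction was divided into the whole run and its parts after these 2 genes were seen. Copy number differences of parts of the run may still account for it, with 85.7% of its genes above the median level lower. So may regulation by ISL1. Across the 17 genes the differences at 0 h and at 48 h as labelled had r = -0.732, and 11 were higher at 48 h, but fixed copy numbers under exchanged 48 h labels would leave such a value too. These cannot be told apart, because no DNA was measured.

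Zinc finger genes were lower soon after induction. Of 347 genes with a Zfp symbol 149 fell and 8 rose at 1 h (median -0.25, camera adjusted p = 5.61e-29, and adjusted p = 0.0606 with an estimated correlation). At 2 h 193 fell and 31 rose (median -0.30, camera adjusted p = 2.97e-12, and adjusted p = 0.377 with an estimated correlation). At 4 h the median was -0.11, and quantile normalization again or median centring left the median at 2 h at -0.27 and -0.26. The array spread as the cause is argued against by a median at 2 h of -0.278 with the spread as a covariate. Low expression by itself did not give such a median: of 10000 random lists matched on mean level none was as low (lowest -0.064). The permutation p of 1e-04, the smallest they can give, is no independent support, because the list was chosen from these data. The draws also took no account of correlation within the family. No biological explanation was tested.

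The splits of the arrays were counted for each comparison of 3 arrays with 3, where 10 splits are too few for a share under 0.05. In each, 1 split of the 10, the real one, gave as many genes as the real count. A mixed split puts a difference between the groups into the residual variance, so its count is low wherever the groups differ. The gap between the counts therefore does not measure the strength of a difference. The real counts and the highest of the other splits were 255 and 0 at 0.5 h, 1410 and 1 at 1 h, 5649 and 1 at 2 h, 7990 and 0 at 4 h, 9187 and 0 at 8 h, and 7342 and 0 for the arrays labelled vector 48 h, all against 0 h. For the steps they were 718 and 1, 4133 and 5, 5579 and 0, 4767 and 0, and 7310 and 1, in order of time. For ISL1 against vector they were 5119 and 0 at 0 h and 5553 and 0 at 48 h as labelled, and for the arrays labelled ISL1 48 h against ISL1 0 h 8590 and 0. For any change over the vector times, 1 of 100 random assignments of the arrays to times, the real one, gave as many as 11256 genes and the highest other 3464. This is the smallest share these draws can give. It bears only on random assignment and not on a batch shared by the arrays of a time.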
